A study of Arabidopsis thaliana with 15 samples.

How the data were processed

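Transcript levels were measured by array in mature Arabidopsis thaliana leaves of 5 groups, each with 3 biological replicates, which gave 15 arrays. The groups were Col-0 at 0, 6 and 10 h and the rps2 mutant at 0 and 10 h after infiltration with Pseudomonas syringae pv. maculicola carrying AvrRpt2, and each array was assigned to its group from its label. The labels name no mock infiltration, clock time, rps2 allele, hybridisation batch or pairing between groups.

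The deposited values are on the log2 scale. Per the labels, the submitters processed the arrays with RMA, a method that corrects the background, quantile-normalises the arrays and summarises the probes of each probe set. All 22810 probe sets in the deposited table had a median of exactly 0 over the arrays, so each value is a log2 difference from that probe set's own median and carries no absolute level. The values ran from -8.93 to 7.49. No further scaling was applied. Because the values hold no signal over background, no detection limit can be given, and the number of arrays limits the precision.

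The 64 control probe sets were set aside and 22746 probe sets were tested. Of these, 13513 were paired with a single gene by the platform's annotation, 503 with several genes, and 8730 had no entry there and therefore carry no gene name here. Gene symbols were taken from a gene table, in which 13436 of the single-gene probe sets were found, and 1580 had a symbol other than the locus code. For the 152 genes with more than 1 single-gene probe set, the mean of these probe sets was used. The design had called for the brightest probe set, which cannot be chosen from centred values. RPS2 and PR1 had been chosen as genes to report but had no named probe set, and they are not analysed here.

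A linear model with a mean for each of the 5 groups was fitted to each probe set with limma 3.58.1 in R 4.3.3, and limma's moderated test was applied with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The test is two-sided. The residual degrees of freedom were 10, and the prior degrees of freedom were 2.31. The p-values measure the spread between biological replicates as labelled. There were 7 comparisons: 6 h against 0 h, 10 h against 0 h and 10 h against 6 h in Col-0, 10 h against 0 h in rps2, rps2 against Col-0 at 0 h and at 10 h, and the interaction, which is the 10 h change of Col-0 less that of rps2. An error after ± is the standard error of the fitted log2 change unless SD is written.

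Gene lists on defence, hormones, photosynthesis, growth and cell types, 27 in all with 396 members, were fixed before the data were examined. Of the members, 53 had a named probe set and 1 carried a name that belongs to another locus. The 7 lists with at least 3 measured members were tested as sets with camera at a preset correlation between genes of 0.01, and their p-values were adjusted over these lists within each comparison. From the smaller lists single genes are named, and 5 lists had no measured member. A further 39 families of at least 4 genes were defined from the gene symbols after the annotation had been read and before their values were examined, and these were adjusted over the families. The genes named from each comparison were the 10 with the largest rise and the 10 with the largest fall (5 and 5 for Col-0 10 h against 6 h and for the genotypes at 0 h) among those past the threshold whose groups did not overlap, and up to 4 members of each fixed list with the largest change. The text names fewer of these, in rank order.

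The alternatives covered fits of only the groups compared, the replicate number as a block, trended and robust variance, array weights (with statmod 1.5.0), a repeated quantile normalisation, centring of arrays on their medians, probe sets of shared transcripts left out, stricter thresholds, each array left out in turn, and camera with an estimated correlation or fry in its place. The fits without rps2 10 h replicate 3 for the comparisons it is not part of, the counts without it at a log2 change of at least 1, the rule for named genes applied to the fit without it, and the centring of arrays on the 24 probe sets of the poly-A spike-ins were added after the data had been seen. A filter on low values was left out, since the mean of centred values does not measure abundance. The similarity of the 6 h and 10 h changes was set against 20 simulations of the shared 0 h arrays.

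The steps were tested on simulated data for Col-0 at 6 h against 0 h with 22746 probe sets. Of 100 probe sets changed by 0.5, 74% were recovered with a mean fitted change of 0.52, and of 100 changed by 1, 100% were recovered with a mean fitted change of 0.99. There were 14 false calls. The noise was drawn with the spread between replicates found without rps2 10 h replicate 3. In the data the median standard error was 0.12 with that array and 0.098 without it. Recovery at the spread of all arrays was therefore not tested. Among 100 unchanged sets of 5 genes, 4% were called, against 100% of the raised sets. The simulated genes varied independently of each other, so the 4% does not cover lists of correlated genes.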

Results

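The series measured transcripts in mature leaves of Arabidopsis thaliana wild type (Col-0) and the rps2 mutant. RPS2 is the resistance protein that recognises the action of AvrRpt2, an effector that the bacterium delivers into the plant cell. Leaves were infiltrated with Pseudomonas syringae pv. maculicola carrying AvrRpt2. Col-0 was sampled at 0, 6 and 10 h and rps2 at 0 and 10 h, with 3 biological replicates in each of the 5 groups. Every comparison of times carries both the infiltration and the change in time of day, since there was no mock-infiltrated group. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.12 on the log2 scale. The genes RPS2 and PR1 are not analysed here.

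Of the 3 rps2 arrays labelled 10 h, replicates 1 and 2 resembled each other and replicate 3 resembled the rps2 0 h arrays. The SD of the difference between replicates 1 and 2 was 0.21 over all probe sets. Replicate 3 differed from both by an SD of 0.942 or 0.949, and from the rps2 0 h arrays by 0.17 to 0.20. UGT76B1 stood at -7.56 relative to its median in this array and between -7.72 and -7.61 in the rps2 0 h arrays, and PUB23 stood at -4.26 against -4.23 to -4.09. Along the 10 h change of the other rps2 arrays, replicate 3 had a slope of 0.00839, where the other rps2 10 h arrays had 0.983 and 0.968. The array also widens the spread shared by all groups, so that the SE of UGT76B1 was 1.45 with it and 0.19 without it in Col-0 at 6 h. The test of all 15 arrays was kept as planned, and for each comparison that involves rps2 at 10 h the count and the medians of the fixed lists called are also given without this array. Medians of the gene families are given over all arrays.

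**Figure D1:**
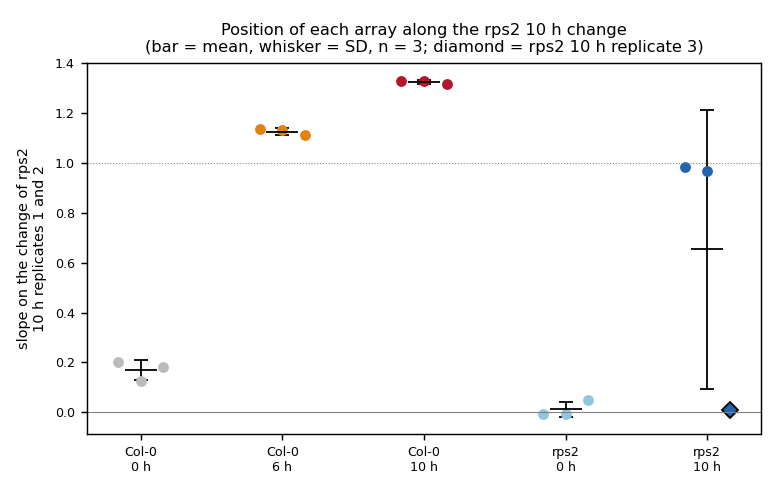
Each point is an array, placed by the slope of its difference from the rps2 0 h mean on the change of rps2 10 h replicates 1 and 2 (vertical axis, no unit). Bars are means and whiskers SD (n = 3). Col-0 arrays lay at 1.11 to 1.14 at 6 h and at 1.32 to 1.33 at 10 h, and rps2 10 h replicate 3 (diamond) lay at 0.00839 among the rps2 0 h arrays.

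The spiked poly-A transcripts dap, lys, phe and thr, which are added to the RNA before labelling, gave higher values on the Col-0 10 h arrays. Their mean was 0.98 ± 0.13 (SD, n = 3) there, and the highest of the other 12 arrays stood at 0.12. The bioC, bioD and cre controls, added at hybridisation, rose by 0.13 between Col-0 0 h and 10 h, where the poly-A controls rose by 1.08. The bioB control, also added at hybridisation and in the lowest amount, rose by 0.49, and it was kept apart from the other 3. The deposited scaling sets the arrays to a like distribution, so every change below is relative to the other transcripts of the same leaf. With arrays centred on the poly-A controls instead, the median change of all probe sets moved from its deposited value by -1.08 in Col-0 at 10 h against 0 h, -1.11 at 10 h against 6 h, 0.29 in rps2, -0.16 between genotypes at 0 h, 1.2 between genotypes at 10 h and -1.37 in the interaction. In Col-0 at 6 h against 0 h it moved by 0.04.

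**Figure D2:**
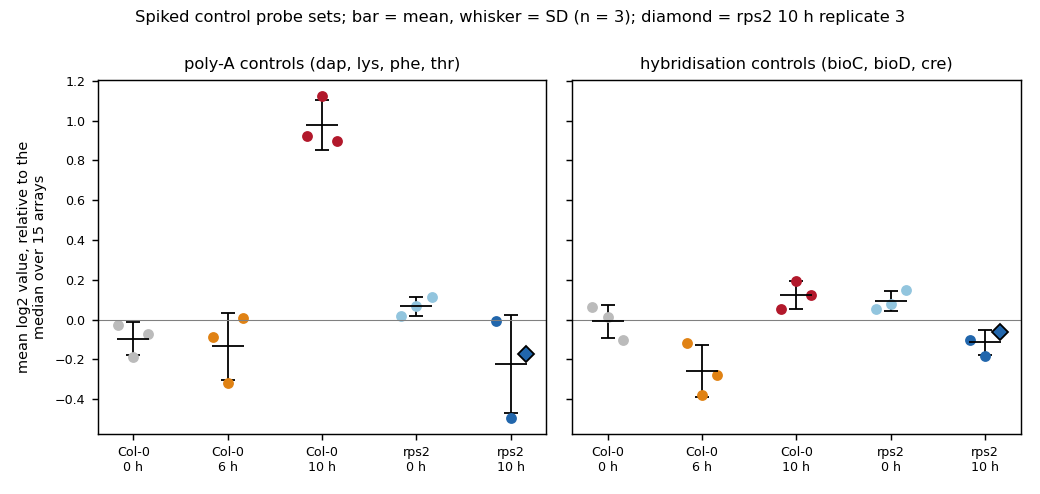
Each point is the mean log2 value of the poly-A controls (left, 24 probe sets) or of the bioC, bioD and cre controls (right, 12 probe sets) on an array, relative to their medians over the 15 arrays. Bars are means and whiskers SD (n = 3), and the diamond is rps2 10 h replicate 3. The Col-0 10 h arrays stood at 0.90 or more in the poly-A controls. The bioB control, which rose by 0.49 in Col-0 at 10 h, is not drawn.

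Col-0 at 6 h against 0 h addresses the early response of leaves with RPS2. UGT76B1 (AT3G11340), which glucosylates salicylic acid and N-hydroxypipecolic acid, rose by 8.54 ± 1.45 on the log2 scale (SE, n = 3 per group here and in the comparisons that follow, unless stated). AT3G01830 and AT4G39670 rose by 7.83 ± 1.15 and 7.80 ± 1.0. AT5G16030, AT2G10940 and the expansin gene EXPA8 (AT2G40610) fell by 5.82 ± 0.78, 5.73 ± 0.44 and 5.42 ± 0.87. In total 12305 of 22746 probe sets changed, 5806 up and 6499 down, and 6446 changed by at least 1 on the log2 scale.

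All 5 measured members of the pattern-triggered immunity list rose at 6 h, none fell, and the count was 5 when adjusted over the list alone (median 2.81, camera adjusted p = 0.00311, but adjusted p = 0.197 with an estimated correlation). The ubiquitin ligase genes PUB23, PUB24 and PUB22 rose by 4.61 ± 0.83, 4.00 ± 0.52 and 2.61 ± 0.28, and their products are known to dampen this form of immunity. BIK1, encoding a kinase downstream of the pattern receptors, rose by 2.81 ± 0.20. The 3 measured WRKY genes rose, 3 of 3 adjusted over the list alone (WRKY53 by 5.35 ± 0.52, WRKY6 by 4.33 ± 0.49, WRKY22 by 1.60 ± 0.25). Camera gave adjusted p = 0.0152 for them, and adjusted p = 0.0971 with an estimated correlation. The 5 measured autophagy genes rose as well, 5 of 5 adjusted over the list alone, with a median of 1.93 (adjusted p = 0.00311, but adjusted p = 0.0971 with an estimated correlation). All 5 are ATG8 genes, and over the 9 genes of the ATG8 family the median was 0.59. ATG8H and ATG8B, whose products coat autophagosomes, rose by 2.66 ± 0.23 and 2.58 ± 0.13.

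Photosynthesis genes fell at 6 h. The 6 measured genes of the light reactions fell, 6 adjusted over the list alone, with a median of -1.59 (adjusted p = 0.00381, but adjusted p = 0.197 with an estimated correlation). LHCB4.2, an antenna protein of photosystem II, fell by 2.79 ± 0.56, and PSBY and PSAN fell by 2.07 ± 0.21 and 2.04 ± 0.29. The 3 Calvin-Benson genes fell, 3 adjusted over the list alone, with a median of -2.69 (adjusted p = 0.00754, but adjusted p = 0.197 with an estimated correlation). These were PRK at -2.77 ± 0.17, SBPASE at -2.69 ± 0.21 and RCA at -1.24 ± 0.11. The auxin list moved both ways, with 1 up, 1 down and 2 not past the threshold (2 up and 1 down adjusted over the list alone, adjusted p = 0.377). GH3.3, which conjugates auxin to amino acids, rose by 4.36 ± 0.47 and the auxin repressor gene IAA29 fell by 3.46 ± 1.14. Of the 3 flavonoid genes, 2 fell and 1 was not past the threshold, also adjusted over the list alone (adjusted p = 0.153), with UGT78D1 at -3.06 ± 0.36.

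Among genes of lists too small to test, GRX480 and SAG101 of the salicylic acid list rose by 5.82 ± 1.05 and 2.83 ± 0.23. AT5G52810, an enzyme of pipecolic acid synthesis, rose by 5.17 ± 0.64, and the co-chaperone gene SGT1A rose by 3.27 ± 0.22. ATERDJ3B and BZIP60, which serve protein folding in the endoplasmic reticulum, rose by 3.18 ± 0.48 and 2.97 ± 0.32. BCAT4, which elongates methionine for aliphatic glucosinolates, fell by 3.46 ± 0.37, and the clock gene GI fell by 1.80 ± 0.60. The guard cell gene FMA and the sugar transporter gene SWEET11 of phloem fell by 0.59 ± 0.10 and 0.81 ± 0.11. Camera was run with a preset correlation, and with a correlation estimated from the residuals 0 of the 26 calls over the 7 lists and 7 comparisons held. These residuals include those of rps2 10 h replicate 3. With fry, which tests the listed genes without setting them against other genes, 39 list results kept their side of the threshold and 10 more passed it. With rps2 10 h replicate 3 left out, the light reactions held with an estimated correlation in 4 comparisons: at 10 h against 0 h (adjusted p = 0.0457), 10 h against 6 h (0.0075), between genotypes at 10 h (0.0212) and in the interaction (0.0216).

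By 10 h against 0 h in Col-0, 13588 probe sets had changed, 6651 up and 6937 down. AT4G39670 rose by 8.52 ± 1.0, the carboxylesterase-like gene AT1G68620 by 8.31 ± 0.88 and UGT76B1 by 8.30 ± 1.45. AT1G26380, a berberine bridge enzyme-like oxidoreductase, rose by 7.90 ± 0.61. LHCB4.2 fell by 6.90 ± 0.56, EXPA8 fell by 6.75 ± 0.87 and AT5G62360 fell by 6.74 ± 0.36. PORB, which makes chlorophyllide in the light, fell by 6.31 ± 0.43.

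The pattern-triggered immunity genes all rose at 10 h, 5 of 5 also adjusted over the list alone (median 4.03, adjusted p = 0.00381, but adjusted p = 0.164 with an estimated correlation). PUB23 rose by 5.73 ± 0.83, PUB24 by 4.85 ± 0.52, BIK1 by 4.03 ± 0.20 and PUB22 by 3.79 ± 0.28. The WRKY genes rose, 3 of 3 also adjusted over the list alone (median 5.21, adjusted p = 0.0132, but adjusted p = 0.126 with an estimated correlation), with WRKY6 at 5.65 ± 0.49. In the autophagy list 4 genes rose and 1 was not past the threshold, also adjusted over the list alone (median 1.76, and 0.68 on the poly-A scale, adjusted p = 0.00539, but adjusted p = 0.126 with an estimated correlation). Over the 9 genes of the ATG8 family the median was 0.58, and -0.50 on the poly-A scale. All 6 light-reaction genes fell, also adjusted over the list alone (median -3.57, adjusted p = 2.05e-04, but adjusted p = 0.148 with an estimated correlation), with PSAN at -4.73 ± 0.29 and PSBY at -4.04 ± 0.21. The Calvin-Benson genes fell, 3 of 3 also adjusted over the list alone (median -4.17, adjusted p = 0.00381, but adjusted p = 0.148 with an estimated correlation). GH3.3 rose by 6.92 ± 0.47 within an auxin list that had 2 up, 1 down and 1 not past the threshold, also adjusted over the list alone (median 0.74, adjusted p = 0.297), a median that turned to -0.34 on the poly-A scale. Of the flavonoid genes 2 fell and 1 was not past the threshold, also adjusted over the list alone (adjusted p = 0.297). GRX480, AT5G52810 and CCR2, the last a cinnamoyl-CoA reductase gene, rose by 6.51 ± 1.05, 3.70 ± 0.64 and 6.32 ± 0.67. BCAT4 fell by 5.25 ± 0.37 and COR15A, a cold-induced chloroplast protein gene, by 3.36 ± 0.44.

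The changes of Col-0 at 6 h and 10 h ran together over the probe sets (r = 0.929, rho = 0.889), of which 4960 were up at both times, against 1698 by chance, and 5689 down at both, against 1982 by chance. Probe sets up at 6 h and down at 10 h numbered 100, against 1771 by chance, and those down and then up numbered 62, against 1900 by chance. Both changes were taken from the same 0 h arrays, and probe sets are not independent replicates. Simulated noise around shared 0 h arrays gave r = 0.497 but a covariance of 0.00728, against 2.12 in the data.

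For probe sets changed in Col-0, 10 h against 6 h, limma gave 6801, 2897 up and 3904 down. The number depended on the scaling: it was 2064 after repeated quantile normalisation, 949 up and 1115 down, and 20972 on the poly-A scale, 430 up and 20542 down. The repeated quantile normalisation gives centred values an equal spread on all arrays. Their SD was 1.07 to 1.13 on the Col-0 10 h arrays and 0.74 to 0.79 at 6 h, so the step also alters differences between these groups. The helix-loop-helix gene AT2G22760 rose by 5.65 ± 0.19, BSMT1 (AT3G11480), a methyltransferase that acts on salicylic acid, by 5.60 ± 1.15 and the beta-glucosidase gene BGLU27 by 5.11 ± 0.28. LHCB4.2 fell by 4.11 ± 0.56, AT4G16880 by 3.62 ± 0.51 and AT3G44450 by 3.38 ± 0.53. SGT1A, which had risen at 6 h, fell by 2.33 ± 0.22. The light-reaction genes fell further, 6 of 6 also adjusted over the list alone (median -2.01, and -3.13 on the poly-A scale, adjusted p = 1.84e-07, but adjusted p = 0.169 with an estimated correlation). The Calvin-Benson genes also fell, 3 of 3 and 3 adjusted over the list alone (median -1.49, and -2.60 on the poly-A scale, adjusted p = 7.48e-04, but adjusted p = 0.169 with an estimated correlation). BIK1 and PUB22 of the pattern-triggered immunity list rose by 1.22 ± 0.20 and 1.18 ± 0.28, but on the poly-A scale their changes were 0.10 and 0.06, not past the threshold. The other 3 members were not past the threshold, also adjusted over the list alone (list median 1.12, 0.36 after quantile normalisation and 0.0065 on the poly-A scale, adjusted p = 0.213). WRKY22 rose by 2.06 ± 0.25, and by 0.94 on the poly-A scale, the other 2 WRKY genes were not past the threshold, and 2 genes were up adjusted over the list alone (list median 1.32, 0.40 after quantile normalisation and 0.21 on the poly-A scale, adjusted p = 0.207). In the autophagy list 2 genes rose and 3 were not past the threshold, and its median (-0.0025) and mean (0.32) differed in sign. On the poly-A scale its median was -1.12, and of the 2 that rose ATG8H was at 0.06 and ATG8E turned to -0.36. GH3.3 rose by 2.56 ± 0.47, and by 1.45 on the poly-A scale.

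The change of rps2 between 0 h and 10 h addresses the response of the mutant, whose allele the labels do not name. For probe sets changed in rps2, 10 h against 0 h, limma gave 0 over all arrays, with 8726 at an unadjusted p under 0.05 and a smallest adjusted p of 0.052. Array weights gave 11632 calls and the trended and robust fit 3921. Without rps2 10 h replicate 3 (n = 2 at 10 h), 10937 probe sets changed, 4820 up and 6117 down, of which 3467 changed by at least 1. The changes in the next sentences come from that fit, whose names were chosen after the data had been seen. JRG21 and AT5G05600, both 2-oxoglutarate-dependent dioxygenases that hydroxylate jasmonic acid, rose by 8.18 ± 0.39 and 6.87 ± 0.57. UGT76B1 rose by 7.68 ± 0.21, and the chitinase-like genes AT2G43620 and CHI rose by 7.29 ± 0.37 and 6.62 ± 0.26. IAA29 fell by 5.70 ± 0.24, AT5G62280 fell by 5.44 ± 0.27 and AT5G12050 fell by 5.36 ± 0.25.

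Lists in rps2 at 10 h showed the same split between all arrays and the fit without replicate 3. Over all arrays 0 of the 5 pattern-triggered immunity genes passed the threshold and 5 were up adjusted over the list alone (median 0.77, adjusted p = 0.00325, but adjusted p = 0.403 with an estimated correlation). Without replicate 3 all 5 rose, with PUB23 at 4.2 ± 0.11, PUB24 at 2.87 ± 0.12 and BIK1 at 1.06 ± 0.13 (median 1.06, adjusted p = 9.13e-04, but adjusted p = 0.0815 with an estimated correlation). Of the light-reaction genes 0 passed over all arrays and 5 were down adjusted over the list alone (median -0.54, and -0.25 on the poly-A scale, adjusted p = 0.00933, but adjusted p = 0.403 with an estimated correlation). Without replicate 3 all 6 fell, LHCB4.2 by 2.81 ± 0.17 (median -0.80, adjusted p = 0.00378, but adjusted p = 0.0815 with an estimated correlation). Over all arrays 0 of the 3 Calvin-Benson genes passed and 3 were down adjusted over the list alone (adjusted p = 0.107), and without replicate 3 all 3 fell (median -0.64, adjusted p = 0.0871). Among the WRKY genes 0 passed over all arrays, with 2 up and 1 down adjusted over the list alone (adjusted p = 0.311), and without replicate 3 WRKY53 rose by 2.61 ± 0.24, WRKY6 rose by 2.49 ± 0.18 and WRKY22 fell by 1.22 ± 0.13. In that fit BSMT1 rose by 5.91 ± 0.25, GRX480 by 5.47 ± 0.14, AT5G52810 by 3.41 ± 0.11 and COR15A by 2.24 ± 0.17, while GI fell by 2.76 ± 0.13. The auxin, flavonoid and autophagy lists had 0 genes past the threshold over all arrays, and adjusted over the list alone 2 auxin genes were down, 1 flavonoid gene was up and 1 down, and 1 autophagy gene was up. Without replicate 3, 2 auxin genes fell, IAA29 among them, and 2 were not past the threshold (adjusted p = 0.0871), while 2 autophagy genes rose and 3 were not past it (adjusted p = 0.212). Of the flavonoid genes 1 rose, 1 fell and 1 was not past the threshold in that fit (adjusted p = 0.926), and their median (-0.14) and mean (0.27) differed in sign.

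**Figure D3:**
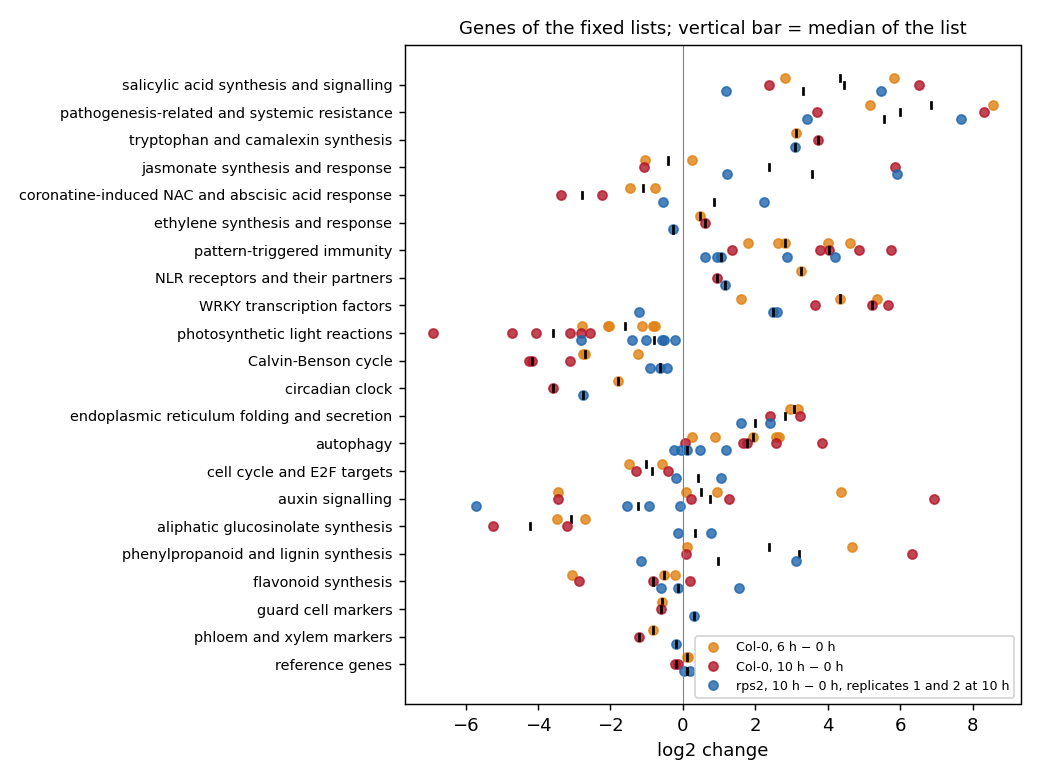
Each point is a measured gene of a gene list fixed before the data were examined, placed by its log2 change in Col-0 at 6 h, in Col-0 at 10 h and in rps2 at 10 h without replicate 3, all against 0 h. Vertical bars are list medians. The pattern-triggered immunity genes lay above 0 in all 3 changes, with medians of 2.81, 4.03 and 1.06, and the light-reaction genes lay below 0, with medians of -1.59, -3.57 and -0.80.

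At 0 h the genotypes already differed. AT1G07050 was lower in rps2 by -6.43 ± 0.80, COR27 (AT5G42900) by -6.06 ± 1.16 and AT4G33980, its relative among cold- and light-regulated clock regulators, by -6.03 ± 0.82. AT5G02540 and AT5G62280 were higher by 4.22 ± 1.0 and 3.75 ± 1.11, and GH3.3 was higher by 3.71 ± 0.47. In all, 3624 probe sets differed, 1875 higher and 1749 lower in rps2, and 6854 did without rps2 10 h replicate 3, which lies outside this comparison but sets the shared spread. For probe sets changed in rps2 against Col-0 at 0 h, repeated quantile normalisation gave 2379 and the poly-A scale 2036, 536 higher and 1500 lower. Of the WRKY genes 2 were higher and 1 was not past the threshold, also adjusted over the list alone (WRKY53 2.29 ± 0.52, WRKY22 1.88 ± 0.25, adjusted p = 0.0267, but adjusted p = 0.15 with an estimated correlation). Of the auxin genes 2 were higher and 2 not past the threshold, also adjusted over the list alone (GH3.3 above and WES1 at 1.95 ± 0.38, median 2.22, adjusted p = 0.0267, but adjusted p = 0.319 with an estimated correlation). The measured members of this list are GH3.1, GH3.3, WES1 and IAA29. Over the 16 genes of the auxin family (IAA, GH3, YUC) the median was 0.23. ATG8E was higher by 1.16 ± 0.15 in an autophagy list with 1 gene higher and 4 not past the threshold, and 2 higher adjusted over the list alone (median 0.22, and 0.05 on the poly-A scale, adjusted p = 0.0304, but adjusted p = 0.244 with an estimated correlation). BIK1 was higher by 0.67 ± 0.20, and the other 4 pattern-triggered immunity genes were not past the threshold. GI was lower by -2.19 ± 0.60, COR15A by -2.99 ± 0.44, UGT78D1 by -1.73 ± 0.36 and BCAT4 by -1.31 ± 0.37. LHCB4.2 differed by 0.14 ± 0.56 and UGT76B1 by -0.48 ± 1.45, neither past the threshold, and 0 of the 6 light-reaction genes passed.

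At 10 h, 12514 probe sets differed between the genotypes, 6109 higher and 6405 lower in rps2. The beta-glucosidase genes BGLU45 and BGLU27 were lower in rps2 by -6.98 ± 0.20 and -6.68 ± 0.28, and AT1G30700 and AT1G26390, further berberine bridge enzyme-like genes, by -6.84 ± 0.15 and -6.55 ± 0.25. AT2G10940, AT5G44680 and AT1G29660 were higher by 5.56 ± 0.44, 5.56 ± 0.22 and 5.50 ± 0.23. The light-reaction genes were higher in rps2, 6 of 6 also adjusted over the list alone (median 3.09, and 2.85 without replicate 3, adjusted p = 3.86e-05, but adjusted p = 0.134 with an estimated correlation). Likewise the Calvin-Benson genes were higher, 3 of 3 also adjusted over the list alone (median 3.92, and 3.61 without replicate 3, adjusted p = 0.00141, but adjusted p = 0.134 with an estimated correlation), with PRK at 3.96 ± 0.17. The pattern-triggered immunity genes were lower, 5 of 5 also adjusted over the list alone (median -2.58, -1.38 on the poly-A scale, -1.55 after quantile normalisation and -1.75 without replicate 3, adjusted p = 0.0143, but adjusted p = 0.235 with an estimated correlation). Autophagy genes were lower in 4 of 5 cases with 1 not past the threshold, also adjusted over the list alone (median -1.24, and -1.06 without replicate 3, adjusted p = 0.0233, but adjusted p = 0.134 with an estimated correlation), and on the poly-A scale the median was -0.03. Over the 9 genes of the ATG8 family the median was -0.61, and 0.60 on the poly-A scale. Of the WRKY genes 2 were lower, and 3 adjusted over the list alone (median -2.62, and -1.42 on the poly-A scale, adjusted p = 0.0711), with WRKY6 at -3.49 ± 0.49. Without replicate 3 the WRKY list had a median of -2.67 and adjusted p = 0.0411, but adjusted p = 0.232 with an estimated correlation. Replicate 3 of rps2 at 10 h stood near the rps2 0 h level in genes of these lists, with LHCB4.2 at 2.56 against 2.50 to 2.59 and WRKY6 at -2.24 against -2.58 to -1.90. Without it 13065 probe sets differed.

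The interaction tested whether the 10 h change depended on genotype, and 10112 probe sets differed in their change, 5096 with the more positive change in Col-0 and 5016 with the more negative. Without rps2 10 h replicate 3 the number was 11773. The change of GH3.3 was 7.39 ± 0.66 more positive in Col-0 than in rps2, BGLU45 by 7.09 ± 0.28 and AT1G30700 by 7.03 ± 0.21. On the other side stood AT5G62360 (-7.85 ± 0.51), AT3G28220 (-7.41 ± 1.58), AT2G43550 (-6.90 ± 1.04), and further down TBL26, COR15B (-5.84 ± 0.39) and BCAT4 (-5.54 ± 0.52). A difference between the genotypes at 0 h enters the interaction. In rps2 at 0 h, GH3.3, WRKY53 and WRKY22 were already higher, and COR15B and BCAT4 already lower, than in Col-0. Among the pattern-triggered immunity genes 4 had the more positive change in Col-0 and 1 was not past the threshold, and 5 were called adjusted over the list alone (median 2.97, adjusted p = 0.0129, but adjusted p = 0.247 with an estimated correlation). Their median was 1.61 on the poly-A scale, and 1.98 without replicate 3, where all 5 were called. BIK1 differed by 3.25 ± 0.28 and PUB22 by 3.11 ± 0.39. All 3 WRKY genes had the more positive change in Col-0, also adjusted over the list alone (median 3.97, 2.60 on the poly-A scale and 3.15 without replicate 3, adjusted p = 0.0172, but adjusted p = 0.0993 with an estimated correlation), with WRKY22 at 4.50 ± 0.35. Autophagy genes had the more positive change in Col-0 in 4 of 5 cases, also adjusted over the list alone, with ATG8H at 3.01 ± 0.32 (median 1.77, 0.40 on the poly-A scale and 1.88 without replicate 3, adjusted p = 0.00543, but adjusted p = 0.0993 with an estimated correlation). Over the 9 genes of the ATG8 family the median was only 0.13, and -1.24 on the poly-A scale. The change of the light-reaction genes was more negative in Col-0, 6 of 6 also adjusted over the list alone (median -3.03, and -2.81 without replicate 3, adjusted p = 3.36e-05, but adjusted p = 0.0993 with an estimated correlation). The same held for the 3 Calvin-Benson genes, also adjusted over the list alone (median -3.57, and -3.25 without replicate 3, adjusted p = 0.00128, but adjusted p = 0.0993 with an estimated correlation). In the auxin list 2 genes had the more positive change in Col-0 and 2 were not past the threshold, also adjusted over the list alone (median 1.29, adjusted p = 0.116), and the median turned to -0.08 on the poly-A scale. Without replicate 3, 3 auxin genes of the list were called (median 2.53, adjusted p = 0.0197, but adjusted p = 0.2 with an estimated correlation). Over all arrays the auxin family of 16 genes had a median of 0.26. Of the flavonoid genes UGT78D1 differed by -3.90 ± 0.51, and 2 were not past the threshold (adjusted p = 0.319).

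Some genes with large changes in both genotypes were not past the threshold of the interaction over all arrays. UGT76B1 differed by 3.14 ± 2.06 (adjusted p = 0.246), BSMT1 by 1.92 ± 1.63 (adjusted p = 0.376) and GI by -1.84 ± 0.84 (adjusted p = 0.0986), with rps2 10 h replicate 3 near the 0 h level in each. Without that array UGT76B1 differed by 0.61 ± 0.28 (adjusted p = 0.0824) and BSMT1 by -0.06 ± 0.33 (adjusted p = 0.902), and GI was past the threshold at -0.81 ± 0.17 (adjusted p = 8.97e-04). Over all probe sets the 10 h changes of Col-0 and rps2 had r = 0.643 (rho = 0.593) and a slope of rps2 on Col-0 of 0.242, and without replicate 3 r = 0.648 (rho = 0.608) and a slope of 0.363. In the latter fit 3508 probe sets were up in both genotypes, against 1499 by chance, and 4510 were down in both, against 2023 by chance. Another 565 were up in Col-0 and down in rps2, against 1903 by chance, and 702 were down in Col-0 and up in rps2, against 1594 by chance. WRKY22 was among the former and COR15A among the latter, with a difference of -5.60 ± 0.23. Both already differed between the genotypes at 0 h, WRKY22 higher and COR15A lower in rps2. These starting differences enter the difference of the changes.

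**Figure D4:**
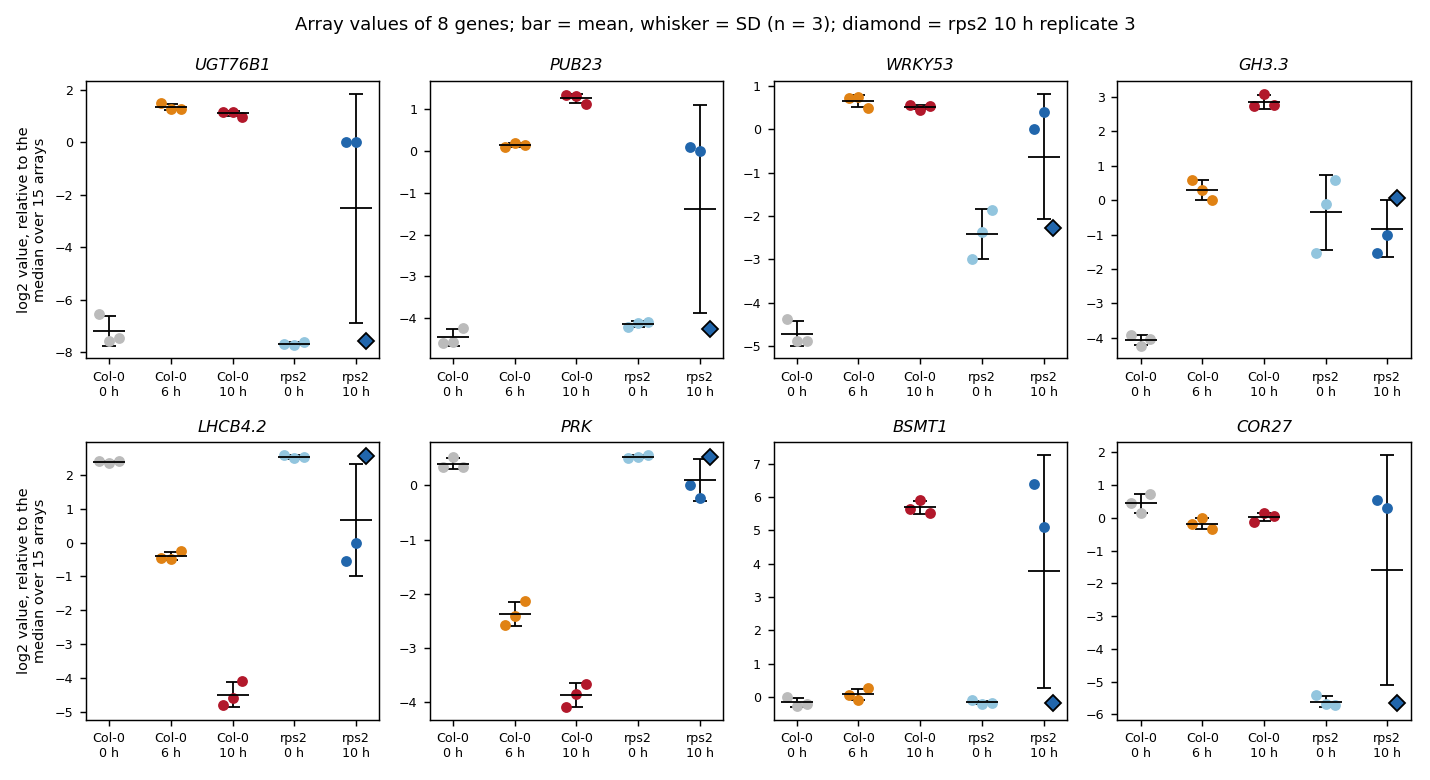
Each point is the log2 value of a gene on an array, relative to that gene's median over the 15 arrays, for 8 genes in the 5 groups. Bars are means and whiskers SD (n = 3), and the diamond is rps2 10 h replicate 3. UGT76B1 stood 8.54 higher at 6 h than at 0 h in Col-0, LHCB4.2 stood -6.90 lower at 10 h than at 0 h in Col-0, and COR27 stood -6.06 lower in rps2 than in Col-0 at 0 h.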

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

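The tests of the array placed among the rps2 0 h arrays, of the spiked controls and of the genotype difference at 0 h were chosen after the result was seen, whereas the interaction and the counts of splits had been planned.

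The interaction showed that 10112 probe sets changed differently by 10 h in Col-0 and rps2. Differences between the genotypes at 0 h enter this count and the medians that follow. The median difference was 2.97 for pattern-triggered immunity, 3.97 for WRKY genes, 1.77 for autophagy, -3.03 for the light reactions and -3.57 for the Calvin-Benson cycle. On the poly-A scale these medians were 1.61, 2.60, 0.40, -4.40 and -4.93, and without rps2 10 h replicate 3 they were 1.98, 3.15, 1.88, -2.81 and -3.25. The measured autophagy list held only ATG8 genes, and over the 9 genes of the ATG8 family the median difference was 0.13, and -1.24 on the poly-A scale. Among the gene families it was 0.98 for mitochondrion-encoded genes, 0.70 for ubiquitin-specific proteases and 0.59 for subunits of the ESCRT complex, and on the poly-A scale these turned to -0.39, -0.67 and -0.77. It was -0.18 for serine carboxypeptidase-like proteins and -0.69 for the family of organelle RNA editing and pentatricopeptide proteins, and on the poly-A scale -1.54 and -2.06. Of 100 drawn splits that exchanged genotypes within a time, 2 gave as many calls, the real split with 10112 included. The other, with 10864 calls, exchanged all arrays at 10 h and none at 0 h. That adds the genotype differences of both times in place of subtracting them, and it points to the large genotype differences in the samples. Splits that mix the genotypes also break these differences, which widens the spread within groups whether or not the 10 h change depends on genotype. The splits therefore cannot tell whether chance gave the count.

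For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05. The real split was the 1 split of 10 with as many calls at 6 h against 0 h (12305), 10 h against 0 h (13588) and 10 h against 6 h (6801) in Col-0 and between genotypes at 0 h (3624) and 10 h (12514), and the highest other split gave 0 in each. For rps2 at 10 h against 0 h the real split gave 0, so all 10 splits gave as many, and the highest other gave 5094. That split sets rps2 10 h replicates 1 and 2 with rps2 0 h replicate 3 against the other arrays, and so points to a structure of the samples, in which replicate 3 at 10 h stands with the 0 h arrays.

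The array labelled rps2 10 h replicate 3 lay with the rps2 0 h arrays, with a slope of 0.00839 along the 10 h change of the other rps2 arrays. Poor hybridisation or degraded RNA is argued against by the SD of its difference from the nearest rps2 0 h array, 0.17, below the range between replicates of the other groups (0.178 to 0.251). An exchange with an rps2 0 h array needs a partner at the 10 h level, and the largest slope among these arrays was 0.0479. RNA of an rps2 leaf sampled at 0 h or a wrong label may account for the array. The slope near 0 is what either needs. A leaf that was infiltrated and did not respond stays open: GI, which fell in the other rps2 arrays, stood at 0.0906 in this array, and no gene in the series marks the time of day apart from the infection.

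The poly-A controls were set apart from the comparisons and rose by 1.08 in Col-0 at 10 h against 0 h, with a gap of 0.78 between the lowest Col-0 10 h array and the highest of the other 12 arrays. Brighter hybridisation or scanning of a whole array is removed by the quantile normalisation in RMA, so these controls cannot test it. The bioC, bioD and cre controls rose by 0.124 of the rise of the poly-A controls. The bioB control rose by 0.458 of it, and its highest Col-0 10 h array (0.57) stayed below the lowest of the poly-A controls (0.90). Controls added at hybridisation thus did not share the full rise. Why bioB was higher in this group than in the others was not tested. Less leaf mRNA per amount of total RNA in Col-0 at 10 h could give this gap, and so could a larger spike-in added to these 3 samples. These cannot be told apart, because the Col-0 10 h arrays are a single group and no independent measure of mRNA was made.

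The genotypes differed at 0 h by 3624 probe sets. An infection-like state of the rps2 leaves at 0 h may account for part of this, but the test cannot tell. Over these probe sets the 0 h difference and the 6 h change of Col-0 were taken from separate Col-0 0 h arrays. Their r was 0.496, 0.507 and 0.530 over the 3 choices of arrays, on both sides of the bound of 0.5 set for the test. The 6 h change also carries the time of day, and the probe sets were called with all Col-0 0 h arrays. Along the change of rps2 10 h replicates 1 and 2, the Col-0 0 h arrays had slopes of 0.126 to 0.202. The rps2 0 h arrays had -0.00592 to 0.0479, near 0 by construction, since slopes are measured from their mean. That mean enters both the difference and the change, which can raise the slopes of the Col-0 arrays. The slopes therefore cannot tell which genotype lay closer to the 10 h state. WRKY53, WRKY22 and BIK1 were higher in rps2 at 0 h. A difference in the time of day at harvest could also shift clock-linked genes, and the smaller of the differences of GI and COR27 was 2.19 in size. Neither can be told from lasting effects of the mutation or of growth, because the rps2 plants and their harvest are confounded in the design.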

How the results depend on the processing

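The fits without rps2 10 h replicate 3 for the comparisons it is not part of, the counts without it at a log2 change of at least 1, the rule for named genes applied to the fit without it and the poly-A scale were chosen after the result was seen. Among the counts and summaries 129 values kept their side of the threshold or stayed within 1.5 times the value over all arrays, as did 4263 of the values of named genes and 603 of those of lists. The others were 17 lower counts, 14 higher counts and 4 similarities that moved. Of the gene values 106 lost the threshold, 158 gained it and 15 reversed, and of the list values 33 lost and 22 gained it. Single arrays left out gave 2800 of the gene values and 355 of the list values that stayed. Replicate numbers did not pair the samples (same-number r from -0.290 to 0.256, mean -0.015), and with the replicate number as a block the probe sets changed in Col-0, 10 h against 0 h numbered 13401 and the gene list shifts stayed at 26. Gene list shifts numbered 26 of 49, and 0 with an estimated correlation. With fry, 39 of the list results kept their side of the threshold and 10 more passed it. Without a single array the count of probe sets changed in rps2, 10 h against 0 h ran from 0 to 10937, the latter without rps2 10 h replicate 3, whose departure widens the shared spread, and that of probe sets changed in rps2 against Col-0 at 0 h ran from 2519 to 6854, the latter without the same array. The similarity of the 10 h responses of Col-0 and rps2 (0.643) ran from 0.605 to 0.658, was 0.705 over probe sets changed in either genotype and 0.554 after repeated quantile normalisation. For probe sets changed in rps2, 10 h against 0 h, the trended fit gave 3921, array weights 11632 and quantile normalisation 6715. For probe sets changed in rps2 against Col-0 at 0 h, a fit of only these groups gave 6856, array weights 7385, quantile normalisation 2379 and an adjusted p under 0.01 gave 2056. Quantile normalisation, which makes the spread of centred values equal on all arrays, gave 2064 for probe sets changed in Col-0, 10 h against 6 h. Before it, SDs were 0.43 and 0.38 on rps2 10 h replicates 1 and 2 and 1.07 to 1.13 on the Col-0 10 h arrays. The step therefore alters differences between groups, and the values after it are no neutral check. With a log2 change of at least 1, and then also without rps2 10 h replicate 3, the counts were 6446 and 6540 for probe sets changed in Col-0, 6 h against 0 h, 7650 and 7710 at 10 h against 0 h, 2046 and 2283 at 10 h against 6 h, 0 and 3467 in rps2, 1000 and 1229 between genotypes at 0 h, 6003 and 5393 for probe sets changed in rps2 against Col-0 at 10 h, and 6151 and 6163 for probe sets whose 10 h change differs between Col-0 and rps2. The counts at that log2 change are lower than without it by construction, and the rise in rps2 comes with the array left out. On the poly-A scale the counts were 20403 (10 h against 0 h) and 20972 (10 h against 6 h) in Col-0, 4348 in rps2, 2036 and 20521 between genotypes at 0 h and 10 h, and 19815 in the interaction. The rise of the counts that involve Col-0 at 10 h goes with its shift of all probe sets. For the 4348 in rps2 and the 2036 at 0 h, which is a fall, the cause was not tested. That scale also reversed EIN3 (-0.46) and SGT1A (-0.15) in Col-0 at 10 h against 0 h, EIN3 (-0.95), ATG8E (-0.36), PRL (-0.93) and DFR (-0.69) at 10 h against 6 h, SAG101 (0.092), EIN3 (0.97), ATG8E (0.60), DFR (0.82), WES1 (0.86) and HCT (0.73) between genotypes at 10 h, and EIN3 (-0.56), EFR (-0.45) and SGT1A (-1.27) in the interaction. For the other values that moved the cause was not tested. The filter on low values was not run, since centred values hold no abundance, and the signal over background cannot be given.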

Other observations

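The families described here had been defined from gene symbols before their values were examined, whereas the test of the organelle hypothesis was chosen after the result was seen. Calmodulin-like genes, which encode calcium sensors, were among the largest rises of Col-0 at 10 h against 0 h: 6 of 7 rose and 1 was not past the threshold (median 3.78, adjusted p = 0.0271, but adjusted p = 0.399 with an estimated correlation). CML37 rose by 7.01 ± 0.45, CML38 by 6.80 ± 0.38 and CML41 by 4.98 ± 1.12 (SE, n = 3 per group). Of 11 ESCRT genes, which sort membrane proteins for degradation, 9 rose, 1 fell and 1 was not past the threshold at 6 h (median 1.12, adjusted p = 0.00925, but adjusted p = 0.124 with an estimated correlation). VPS60.1 rose by 3.66 ± 0.37 and VPS20.1 by 2.04 ± 0.20, while VPS2.2 fell by 1.01 ± 0.15. Of 12 ubiquitin-specific proteases 9 rose, 1 fell and 2 were not past the threshold at 10 h (median 0.74, adjusted p = 0.0271, but adjusted p = 0.159 with an estimated correlation), a median that turned to -0.34 on the poly-A scale. Of 29 serine carboxypeptidase-like genes 13 fell, 1 rose and 15 were not past the threshold at 10 h (median -0.19, and -1.27 on the poly-A scale, adjusted p = 0.038, but adjusted p = 0.159 with an estimated correlation). Between 6 h and 10 h, 9 of 20 beta-glucosidase genes rose, 1 fell and 10 were not past the threshold (median 0.28, mean 0.97, adjusted p = 9.02e-04, adjusted p = 0.0486 with an estimated correlation), with a median of -0.83 on the poly-A scale. BGLU45 and BGLU46 rose by 3.11 ± 0.20 and 2.89 ± 0.21 in that interval.

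Of 15 genes for organelle RNA editing and pentatricopeptide proteins, 9 fell and 6 were not past the threshold in Col-0 at 10 h (median -0.44, and -1.52 on the poly-A scale, adjusted p = 0.0271, but adjusted p = 0.159 with an estimated correlation), with CRR42, CRR21 and CRR41 at -4.83 ± 0.20, -4.13 ± 0.34 and -3.61 ± 0.27. CRR21 is an editing factor, while CRR41 and CRR42 are known for the assembly of the plastid NDH complex rather than for RNA editing. Of 20 plastid-encoded photosystem genes 15 fell and 5 were not past the threshold at 6 h (median -0.53, adjusted p = 0.0257, but adjusted p = 0.639 with an estimated correlation), with psaJ at -1.77 ± 0.17. Of 9 genes for dehydration and cold proteins 5 were lower and 4 not past the threshold in rps2 at 0 h (median -1.45, adjusted p = 0.00306, but adjusted p = 0.11 with an estimated correlation), with COR27 at -6.06 ± 1.16, COR15B at -3.19 ± 0.28 and LTI30 at -3.19 ± 0.25.

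Of 15 mitochondrion-encoded genes 12 rose and 3 were not past the threshold in Col-0 at 10 h against 0 h (median 1.07, adjusted p = 0.00149, but adjusted p = 0.248 with an estimated correlation), a median that turned to -0.01 on the poly-A scale. Among them cox2 rose by 3.31 ± 0.18 and nad6 by 2.85 ± 0.14. In the interaction with genotype 12 of the 15 had the more positive change in Col-0 (median 0.98, adjusted p = 0.00108, but adjusted p = 0.23 with an estimated correlation), and -0.39 on the poly-A scale. The hypothesis that organelle RNA of every kind made up a larger share at 10 h was tested on the plastid-encoded photosystem genes, whose median change was -0.46, and -1.53 on the poly-A scale, and this argues against it. Mitochondrial transcripts that kept their level while other transcripts fell may give the same pattern, as the median of -0.01 on the poly-A scale would have it, but this rests on equal amounts of spike-in, which stay open.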
